A study of Arabidopsis thaliana with 36 samples.

How the data were processed

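The series holds 36 samples, of which the 12 RNA samples were used. The 8 methylation samples and the 16 chromatin immunoprecipitation samples were not analysed here. Per the labels, seeds were stratified before growth in continuous light and RNA was taken from roots, although the label on RNA isolation names rosette leaves. Groups come from titles and source names (WT control, WT low Pi, *otu5* control, *otu5* low Pi, 3 libraries each). The culture condition label was not used, because it follows the genotype and contradicts the title of 6 libraries.

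The values are the authors' deposited RPKM (by name, reads per kilobase of gene scaled to the mapped reads of the library). The table holds 33557 genes with 1 column per library, each matched to its sample by name. TopHat2 2.0.4, Cuffdiff and TAIR10 are named in the submitters' processing notes, with no role given. Cuffdiff itself writes FPKM, which counts fragments, and how the values were scaled between libraries is not given in the sources used here. Library sums between 993382 and 1330830 show that the values were not made to sum to a fixed total. Median-ratio size factors over the tested genes lay between 0.9991 and 1.001. By this measure the libraries were already level as deposited. Because any scaling sets the level of the typical gene, a change in the total amount of mRNA per cell cannot be seen in these values. How reads were shared between near-identical or overlapping genes, and whether strand was used, is likewise not given, so values of gene families such as LHCB, RBCS, IMA and PHT1 are uncertain in how they split between members. Names and locus lengths were taken from a RefSeq gene table of assembly TAIR10.1, in which 32810 identifiers matched (97.8%). Beyond these lengths and gene order, no coordinates were used.

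The table gives no read counts. Among genes under 0.3 RPKM, the commonest ratio between a library and WT control replicate 1 was held by 24.4% to 28.2% of genes, and it put relative depth between 0.672 and 1. Absolute depth stays unknown, and no counting interval is given. AT2G01021 took between 21532 and 317971 RPKM, the highest value being in WT control replicate 3. Of the tested genes, 35 were at 0 in some library although their median was at least 10 RPKM, and 28 of these have loci under 300 bp, so an exact 0 can be a failed estimate and such genes are said to be listed at 0.

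Values were tested as log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3. Fold changes are on this scale, which understates the change of genes with low values. Genes with at least 1 RPKM in at least 3 of the 12 libraries were tested (20411 genes, with 13146 left out). A single fit of 4 group means over 12 libraries, with 8 residual degrees of freedom and empirical Bayes moderation with trend and robust estimation, gave the 4 pairwise comparisons and the interaction. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. Mean list levels and OTU5 were compared by exact two-sided permutation tests, whose smallest p with 3 against 3 libraries is 0.1.

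There were 25 gene lists with 405 genes, of which 360 genes on 24 lists were tested. They cover Pi signalling and transport, Pi scavenging, lipid remodelling, local Pi and iron sensing, iron uptake, iron storage, root hair growth, root hair fate, meristem and cell cycle, endodermis, suberin, xylem, photosynthesis, auxin, ethylene, jasmonate, immunity, anthocyanin, nitrate, sulfate, heat shock, DNA methylation machinery, the OTU family and reference genes. The remaining list, of reporters silenced by DNA methylation, had 0 members past the expression filter and gave no test. The photosynthesis list serves as a marker of green shoot tissue, and the endodermis and suberin lists serve as markers of root tissue. Named genes are OTU5, the 6 largest rises and 6 largest falls among called genes whose library values do not overlap between groups (which chance alone gives for 10% of genes), and up to 4 called members per list with the largest change. For the interaction the 3 smallest p values are named. Genes given only by identifier are mostly passed over. PHO2, NLA, FRD3, PDR9 and LRL3, which moved against the rest of their list, and the members named in the closing tests were chosen after their values were seen. Groups, tests, lists, this rule and all alternatives except fry, the exclusion of loci under 300 bp and the replicate block in WT only were fixed before the data were examined.

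The procedure was tested on simulated data, 5 runs of 20411 genes with known changes. For WT low Pi against control it recovered 60.3%, 84.8% and 97.3% of genes shifted by 0.5, 1 and 2 on the log2 scale, with 7% of calls false, and for the interaction 30.1%, 74.9% and 93.3%, with 4.3% false. The false share was 4.9% for *otu5* low Pi against control, 4.7% for *otu5* against WT in control and 6% in low Pi. Camera found 20 of 20 shifted lists in the WT low Pi comparison and called 3 of 460 unchanged lists. The simulated genes varied independently, so this rate does not carry over to real lists with correlated members. The ethylene list, for example, had an estimated correlation of 0.49.

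The alternatives were pseudocounts of 0.1 and 1, no filter, a filter of 5 RPKM, median-ratio scaling, quantile normalization, the replicate number as a block, limma without trend and robust estimation, estimated library weights, a fit of only the 6 libraries compared, an estimated correlation and fry for lists, loci under 300 bp left out, and each library left out in turn. The labels give replicates 1 to 3 in every group and name no shared batch or plate. Between WT control and WT low Pi, the deviations of same-numbered libraries from their group means correlated with r of 0.204, 0.259 and 0.114, and those of other libraries with r from -0.175 to -0.02. Only in this pair of groups was every same-numbered r over 0.1, and a replicate block in WT only was added for it. The values do not settle whether the numbers pair the samples. Between *otu5* control and *otu5* low Pi, libraries of unlike number also reached r of 0.179, 0.11 and 0.152.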

Results

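RNA was measured in roots of *Arabidopsis thaliana*, in the wild type (WT) and in the *otu5* mutant, each grown on control medium and on medium low in phosphate (Pi). There were 3 libraries in each of the 4 groups. OTU5 is a deubiquitinating enzyme of the ovarian tumour protease family, and the stated question was what it does in root development and in the changes that Pi starvation brings to the root. Polyadenylated RNA was sequenced with 100-bp reads. Groups were taken from the library titles and source names, which carry the same genotype and medium. The culture condition label instead followed the genotype and contradicted the title in 6 of the 12 RNA libraries. The tissue label and the growth text name roots, while the RNA isolation text names rosette leaves. Each library's deposited RPKM values summed to between 993382 and 1330830. The relative depth read from the lowest values lay between 0.672 in *otu5* control replicate 1 and 1 in WT control replicate 1, the library set as the reference. Pairs of replicates correlated across genes with Pearson's r from 0.969 to 0.983, and at most 0.299% of their values were identical. The labels do not say whether replicates came from separate plants or plates, so p-values measure only the spread between these samples, which may be technical.

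The transcript that the mutation targets was low in every *otu5* library. OTU5 (AT3G62940) was at 40.9 ± 1.9 RPKM in WT control roots and 1.36 ± 0.336 RPKM in *otu5* control roots (SD, n = 3). In low Pi the means were 39.9 ± 0.926 and 0.811 ± 0.329 RPKM. The mutant therefore held 3.32% of the WT level in control medium and 2.03% in low Pi. The log2 differences were -4.49 (SE 0.18, limma adjusted p = 1.1e-06) and -4.98 (SE 0.18, adjusted p = 3.6e-07). An exact two-sided permutation test of OTU5 alone gave p = 0.1 in each medium, the smallest that 3 against 3 libraries allow. Low Pi itself gave OTU5 a log2 difference of -0.03 in WT (adjusted p = 0.95) and -0.52 in *otu5* (SE 0.18, adjusted p = 0.094).

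**Figure D1:**
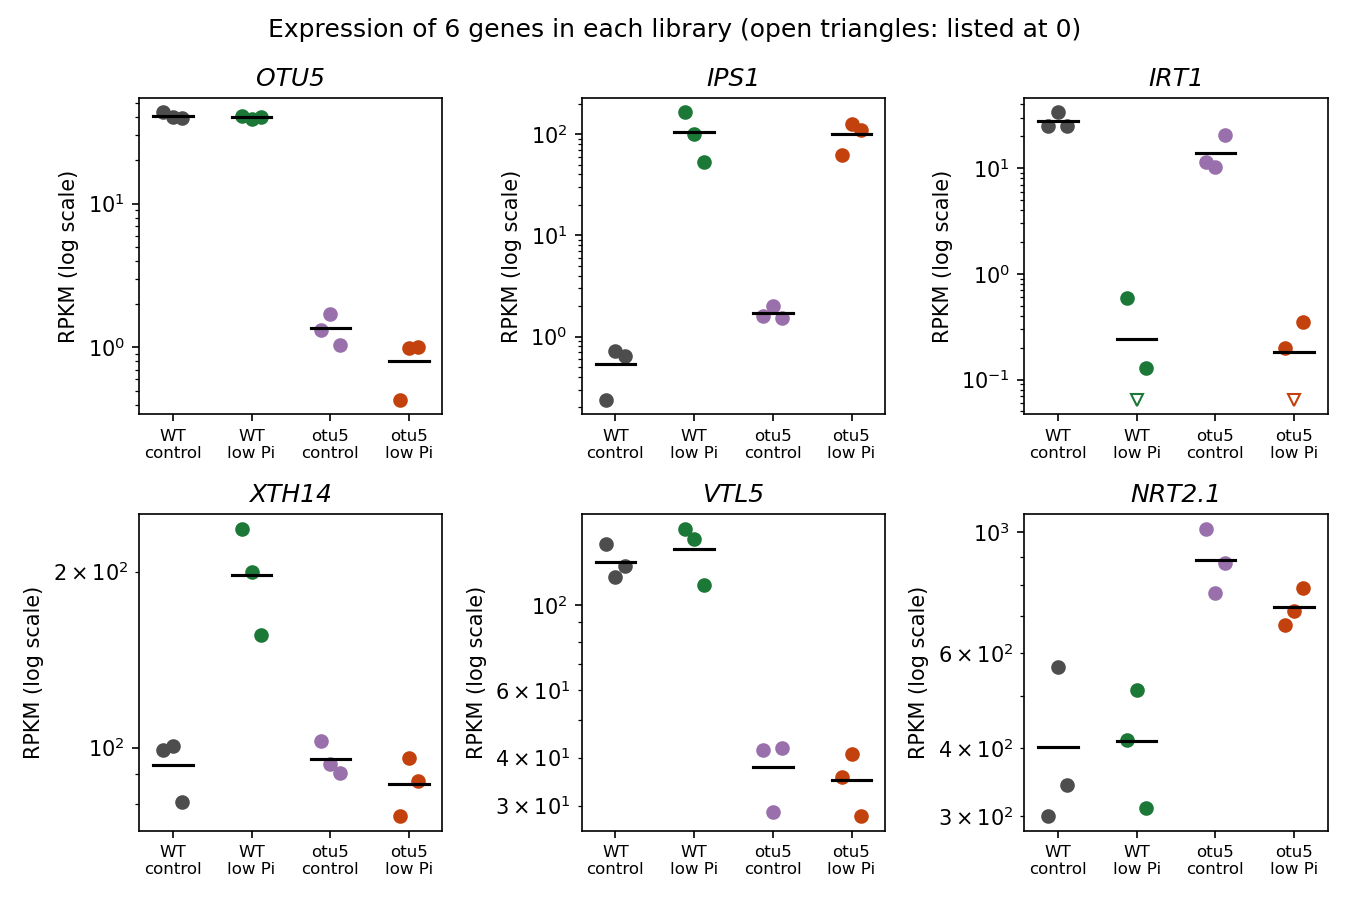
Expression of OTU5, IPS1, IRT1, XTH14, VTL5 and NRT2.1 in RPKM on a log scale, with 1 point per library, a bar at the mean of each group of 3 libraries and open triangles for values listed at 0. OTU5 lies near 40.9 RPKM in WT control and 1.36 RPKM in *otu5* control, and XTH14 is higher in WT low Pi (197 RPKM) than in *otu5* low Pi (86.6 RPKM).

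The comparison of low Pi with control in WT roots gives the response to Pi limitation when OTU5 is intact. The non-coding RNA IPS1 (AT3G09922), a decoy for a microRNA, rose from 0.536 ± 0.261 to 105 ± 55.8 RPKM (SD, n = 3). Its log2 fold change was 6.56 (SE 0.39, limma adjusted p = 3.7e-05). Its relative AT4 (AT5G03545) rose from 82.1 ± 1.99 to 1020 ± 426 RPKM. SPX1, which senses Pi status and restrains the starvation regulator PHR1, rose from 10.9 ± 1.69 to 145 ± 59.6 RPKM (log2 fold change 3.6, SE 0.29, adjusted p = 0.00017). The acid phosphatase gene PAP17 rose from 8.72 ± 0.349 to 84.3 ± 24.9 RPKM (log2 fold change 3.16, SE 0.2, adjusted p = 4.2e-05). The iron transporter gene IRT1 (AT4G19690) moved the other way, from 28.0 ± 4.93 RPKM in control to values of 0.24 ± 0.311 RPKM in low Pi (log2 fold change -5.33, SE 0.33, adjusted p = 3.7e-05). It is listed at 0 in 1 low Pi library.

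Of 22 tested genes of Pi signalling and transport, 13 rose and 2 fell in WT (14 and 2 adjusted over the list alone). As a list they were higher by camera (adjusted p = 2.2e-12, and adjusted p = 0.072 with an estimated correlation). The Pi transporter gene PHT1;2 rose by 3.42 on the log2 scale (SE 0.45). The 2 members that fell were PHO2 (-0.58, SE 0.06) and NLA (-0.49, SE 0.09), both known as repressors of Pi transporters. NLA lost its call without WT control replicate 2 or 3 (adjusted p = 0.057 and 0.08) or WT low Pi replicate 1 or 2 (0.054 and 0.061), which left 1 fall. Of 13 genes of Pi scavenging 9 rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 9.3e-10, and adjusted p = 0.13 with an estimated correlation). They included the phosphatase gene PS2 (2.73, SE 0.34) and the ribonuclease gene RNS1 (2.2, SE 0.23). Of 17 genes of lipid remodelling, by which phospholipids are replaced, 11 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 1.2e-11, and adjusted p = 0.14 with an estimated correlation). GDPD1 rose from 10.9 ± 1.2 to 60.8 ± 23.8 RPKM and the phospholipase gene PLDZ2 from 0.973 ± 0.16 to 4.68 ± 1.54 RPKM. NMT3, which acts in phosphocholine synthesis, was the member that fell, from 174 ± 30.1 to 47.3 ± 12.4 RPKM (log2 fold change -1.89, SE 0.23, adjusted p = 0.0025). In the list of local Pi and iron sensing 1 of 7 genes rose (2 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.01, and adjusted p = 0.13 with an estimated correlation). That gene was ALMT1, which encodes a malate channel, at 2.61 ± 0.293 RPKM in control and 19.2 ± 4.17 RPKM in low Pi (log2 fold change 2.65, SE 0.17, adjusted p = 3.7e-05).

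Iron uptake genes fell with low Pi in WT. Of 24 tested, 10 fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 5.6e-08, and adjusted p = 0.072 with an estimated correlation). The peptide genes IMA1 and IMA2, which promote iron uptake, had log2 fold changes of -2.53 (SE 0.23) and -2.54 (SE 0.26), and the regulator gene BHLH38 had -2.46 (SE 0.22). CYP82C4, a gene of coumarin synthesis, was at 2.51 ± 0.304 RPKM in control and was listed at 0 in all 3 low Pi libraries. FRD3 (0.76, SE 0.15) and PDR9 (0.46, SE 0.08), 2 transporter genes, were the members that rose. FRD3 lost its call without WT control replicate 1 or 3 (adjusted p = 0.081 and 0.092) or WT low Pi replicate 2 or 3 (0.086 and 0.071), which left 1 rise. Of 6 iron storage genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.037, and adjusted p = 0.39 with an estimated correlation). With the replicate block in WT only neither the list (camera adjusted p = 0.071) nor FER4, 1 of the risers (adjusted p = 0.06), passed. The member that fell was VTL2. Without each of the 6 libraries in turn 2 rose and 0 fell, since FER4 (adjusted p from 0.079 to 0.12) and VTL2 (0.058 to 0.11) lost their calls each time, as both did with no filter (0.054 for each). The ferritin gene FER1 went from 102 ± 12.7 to 209 ± 21 RPKM (log2 fold change 1.03, SE 0.14, adjusted p = 0.0034).

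Root hair growth genes rose with low Pi in WT. Of 34 tested, 17 rose and 0 fell (25 and 0 adjusted over the list alone). The list was higher by camera (adjusted p = 6.8e-18, and adjusted p = 0.17 with an estimated correlation). The cell wall gene PRP1 rose from 7.49 ± 0.586 to 21.9 ± 2.53 RPKM, RHS18 from 7.96 ± 0.681 to 20.5 ± 3.02 RPKM, and XTH14, a wall-loosening enzyme gene, from 93.4 ± 10.9 to 197 ± 40.7 RPKM (log2 fold change 1.06, SE 0.14, adjusted p = 0.0035). Photosynthesis genes were lower as a list (camera adjusted p = 8.6e-12, and adjusted p = 0.33 with an estimated correlation). Of 28, 0 rose and 2 fell, while 21 fell adjusted over the list alone. The 2 that fell were RCA, at 95.9 ± 10.2 and 71.4 ± 6.17 RPKM, and GAPB, at 38.5 ± 3.78 and 29.4 ± 2.49 RPKM. GAPB lost its call without WT control replicate 2 (adjusted p = 0.059), WT control replicate 3 (0.068) or WT low Pi replicate 1 (0.058). RCA lost its call without the same 3 libraries (0.07, 0.092 and 0.069) or without WT low Pi replicate 3 (0.071). The mean level of the photosynthesis list differed by -0.34 on the log2 scale (exact permutation p = 0.2), that of the endodermis list by -0.23 (exact p = 0.1, the smallest possible) and that of the suberin list by 0.04 (exact p = 0.8).

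Camera also put the lists of sulfate (adjusted p = 6.8e-05), ethylene (0.00018), jasmonate (0.0026) and immunity (0.01) higher in WT low Pi, and those of the meristem (0.0029), xylem (0.0039) and endodermis (0.0081) lower. With an estimated correlation their adjusted p values were 0.27, 0.36, 0.37, 0.37, 0.42, 0.36 and 0.34. Of 14 sulfate genes 1 rose and 0 fell (7 and 0 adjusted over the list alone), of 16 ethylene genes 1 and 0 (7 and 0), of 10 jasmonate genes 1 and 0 (2 and 0), and of 6 immunity genes 0 and 0 (1 and 0). None of the 22 meristem, 6 xylem or 10 endodermis genes passed in limma over all genes, while 3, 4 and 2 were lower at an unadjusted p under 0.05. Adjusted over the list alone 4 xylem genes fell. In 18 nitrate genes 1 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.053). The nitrate reductase gene NIA1 fell from 537 ± 19.3 to 391 ± 27.1 RPKM. The lists of anthocyanin, auxin, DNA methylation machinery, heat shock, OTU family, reference genes, root hair fate and suberin did not pass. Root hair fate had a camera adjusted p of 0.053, and 0.044 with the replicate block in WT only.

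Over all 20411 genes tested, limma called 875 in WT, 520 higher and 355 lower in low Pi. Of these, 154 and 40 changed by at least 2-fold. Without WT control replicate 1, 2 or 3 the count was 387, 490 or 242, without WT low Pi replicate 2 or 3 it was 324 or 525, and with estimated library weights it was 2005. The iron storage list lost its camera call without WT control replicate 3, WT low Pi replicate 1 or WT low Pi replicate 2 (median log2 fold change 0.28, 0.24 and 0.29), and the endodermis list without WT low Pi replicate 3 (-0.14). With each library left out in turn 4 to 12 lipid remodelling genes rose against 11, 6 to 9 scavenging genes against 9 and 8 to 21 root hair growth genes against 17, and 0 to 6 photosynthesis genes fell against 2. Of sulfate genes 0 to 3 rose against 1, of ethylene and of jasmonate genes 0 to 2 against 1, and of local sensing and of nitrate genes 1 to 2 against 1, while 1 to 2 nitrate genes fell against 2. The lowest of these counts were reached without WT control replicate 3, among others.

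The same comparison in *otu5* roots gives the Pi response when OTU5 transcript is low. IPS1 rose from 1.71 ± 0.273 to 99.7 ± 33.2 RPKM (SD, n = 3; log2 fold change 5.45, SE 0.39, limma adjusted p = 0.00014), SPX1 from 13.2 ± 3.27 to 125 ± 26.2 RPKM and PAP17 from 12.2 ± 1.29 to 81.6 ± 19.1 RPKM. IRT1 was at 14.0 ± 5.58 RPKM in control and 0.182 ± 0.175 RPKM in low Pi, with 1 low Pi library listed at 0 (log2 fold change -4.38, SE 0.33, adjusted p = 0.00014). CYP82C2 and CYP71A12, genes of indolic defence compounds, were among the largest rises, with log2 fold changes of 6.13 (SE 0.89, adjusted p = 0.0044) and 5.42 (SE 0.9, adjusted p = 0.0088). CYP82C2 went from 0.11 ± 0.0541 to 72.8 ± 65.3 RPKM and CYP71A12 from 1.15 ± 0.599 to 107 ± 90.4 RPKM, so that their low Pi libraries differed widely. The log2 fold changes were 5.29 and 4.66 without *otu5* low Pi replicate 2 and 7.38 and 6.55 without replicate 3, and CYP71A12 did not pass in a fit of only these 6 libraries (adjusted p = 0.059). In WT CYP82C2 was also among the largest rises (3.87, SE 0.89, adjusted p = 0.041). That call was lost without WT control replicate 1, 2 or 3 (adjusted p = 0.11, 0.099 and 0.13), WT low Pi replicate 2 or 3 (0.12 for each), with the replicate block in WT only (0.069), with a pseudocount of 1 (0.084) and with quantile normalization (0.052). AIR1, named for its induction by auxin in root cultures, fell from 721 ± 60.4 to 151 ± 55.6 RPKM (log2 fold change -2.31, SE 0.34, adjusted p = 0.0046).

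In *otu5*, 13 of 22 genes of Pi signalling and transport rose and 2 fell (14 and 3 adjusted over the list alone; camera adjusted p = 2.5e-08, and adjusted p = 0.2 with an estimated correlation). AT4 had a log2 fold change of 3.15 (SE 0.25). Of 13 scavenging genes 7 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 5.1e-07, and adjusted p = 0.26 with an estimated correlation), and they included PS2 (2.25, SE 0.34). Of 17 lipid remodelling genes 12 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 1.7e-08, and adjusted p = 0.26 with an estimated correlation). MGD3, which makes galactolipids, rose by 2.05 on the log2 scale (SE 0.36) and NMT3 fell from 160 ± 27.6 to 33.0 ± 8.89 RPKM. In the list of local Pi and iron sensing 2 of 7 rose (2 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.019, and adjusted p = 0.2 with an estimated correlation). ALMT1 had a log2 fold change of 2.31 (SE 0.17). The other, LPR2 (0.35, SE 0.1, adjusted p = 0.047), lost its call without each of the 6 libraries (adjusted p from 0.055 to 0.15), which left 1 gene each time, with no filter (0.063) and with limma without trend and robust estimation (0.062). Iron uptake genes fell, 12 of 24, with 2 that rose (12 and 4 adjusted over the list alone; camera adjusted p = 3.5e-05, and adjusted p = 0.2 with an estimated correlation). The regulator gene BHLH39 fell from 7.18 ± 0.209 to 1.04 ± 0.18 RPKM (log2 fold change -2.32, SE 0.11, adjusted p = 9.3e-06). FRD3 (0.9, SE 0.15) and PDR9 (0.5, SE 0.08) were again the members that rose. Of 6 iron storage genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), and the list itself did not pass (camera adjusted p = 0.2).

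Photosynthesis genes fell in *otu5* with low Pi. Of 28 tested, 16 fell and 0 rose (25 and 0 adjusted over the list alone; camera adjusted p = 1.8e-14, and adjusted p = 0.27 with an estimated correlation). The Rubisco activase gene RCA fell from 138 ± 5.57 to 90.4 ± 6.16 RPKM (log2 fold change -0.61, SE 0.09, adjusted p = 0.0033) and GAPB from 54.8 ± 1.89 to 38.0 ± 1.39 RPKM. The list's mean level differed by -0.47 on the log2 scale (exact permutation p = 0.1, the smallest possible), the endodermis list's by -0.23 (exact p = 0.1) and the suberin list's by 0.33 (exact p = 0.2). Of 34 root hair growth genes 4 rose and 1 fell, both over all genes and adjusted over the list alone, and the list did not pass (camera adjusted p = 0.38). PRP1 rose by 1.03 on the log2 scale (SE 0.19), while XTH14 was at 95.7 ± 6.3 RPKM in control and 86.6 ± 9.79 RPKM in low Pi. The member that fell, LRL3, encodes a root hair regulator and went from 19.5 ± 1.3 to 15.1 ± 0.591 RPKM, a call that was lost without each of the 6 libraries (adjusted p from 0.053 to 0.12). Of the 4 that rose, RHS18 lost its call without *otu5* control replicate 2 or 3 (0.08 and 0.11) or *otu5* low Pi replicate 2 (0.067). LRL1 lost its call without *otu5* control replicate 1 or 2 (0.065 and 0.068) or *otu5* low Pi replicate 1 or 2 (0.084 and 0.083), and with each library left out 2 to 4 rose. In a fit of only these 6 libraries neither RHS18 nor LRL1 passed (0.083 and 0.069). PRP1 and RSL4, which also rose, each lost their call in 1 alternative other than a left-out library, and RSL4 in 1 left-out fit. Sulfate genes rose, 5 of 14 with 0 that fell (9 and 1 adjusted over the list alone; camera adjusted p = 7.3e-05, and adjusted p = 0.27 with an estimated correlation). SULTR1;3 had a log2 fold change of 1.46 (SE 0.25).

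Camera also put the suberin list (adjusted p = 0.0016) and the ethylene list (0.0097) higher in *otu5* low Pi, and the endodermis (0.012) and meristem (0.027) lists lower. With an estimated correlation their adjusted p values were 0.56, 0.69, 0.44 and 0.69. Of 9 suberin genes 2 rose (6 adjusted over the list alone), of 16 ethylene genes 3 rose (6 rose and 1 fell adjusted over the list alone), and 1 of 10 endodermis genes (6 adjusted over the list alone) and 1 of 22 meristem genes (1 adjusted over the list alone) fell. The 2 suberin genes were FAR4 (0.49, adjusted p = 0.05) and GPAT5 (0.47, adjusted p = 0.041). Without *otu5* control replicate 2 or 3 or *otu5* low Pi replicate 1 or 2 the count was 0, without *otu5* low Pi replicate 3 it was 1, and without *otu5* control replicate 1 it was 4. Both lost their calls with no filter (adjusted p = 0.066 and 0.056), with limma without trend and robust estimation (0.064 and 0.053) and in a fit of only these 6 libraries (0.052 and 0.097). The ethylene signalling gene EBF2 rose from 45.7 ± 3.16 to 73.8 ± 12.3 RPKM. Among 18 nitrate genes 1 rose and 3 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.14). The reference gene UBQ10 was at 1360 ± 28.5 RPKM in control and 1740 ± 122 RPKM in low Pi (log2 fold change 0.36, SE 0.06, adjusted p = 0.005). The lists of immunity, auxin, reference genes, DNA methylation machinery, jasmonate, anthocyanin, heat shock, OTU family, xylem and root hair fate did not pass.

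limma called 1754 genes in *otu5*, 982 higher and 772 lower in low Pi. Of these, 218 and 82 changed by at least 2-fold. The count was 1057, 878 or 503 without *otu5* control replicate 1, 2 or 3 and 693 or 682 without *otu5* low Pi replicate 1 or 2, it was 7631 with estimated library weights, and it was 855 in a fit of only these 6 libraries. The meristem list lost its camera call without *otu5* control replicate 2 or 3 (median log2 fold change -0.09 and -0.08) or *otu5* low Pi replicate 1 or 2 (-0.05 and -0.06), the local sensing list without *otu5* control replicate 2 (0.05) and the ethylene list without *otu5* low Pi replicate 2 (0.13). With each library left out in turn 3 to 12 photosynthesis genes fell against 16. Of lipid remodelling genes 5 to 12 rose against 12, of Pi signalling and transport genes 8 to 13 against 13, of sulfate genes 1 to 7 against 5, of ethylene genes 1 to 6 against 3 and of iron storage genes 1 to 3 against 3. The lowest of these counts were reached without *otu5* control replicate 3, among others. Of nitrate genes 0 to 2 rose against 1, and 1 to 2 Pi signalling and transport genes, 0 to 4 meristem genes, 0 to 1 endodermis genes and 0 to 1 iron storage genes fell against 2, 1, 1 and 1.

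Across the 20411 genes, which are not independent replicates, the low Pi responses of the genotypes correlated with Pearson's r of 0.56 and Spearman's rho of 0.55. They share no library. Among genes called in both, 318 were higher in both and 201 lower in both, against 25 and 13.4 for independent lists. Only 3 had opposite signs, against 36.7.

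**Figure D2:**
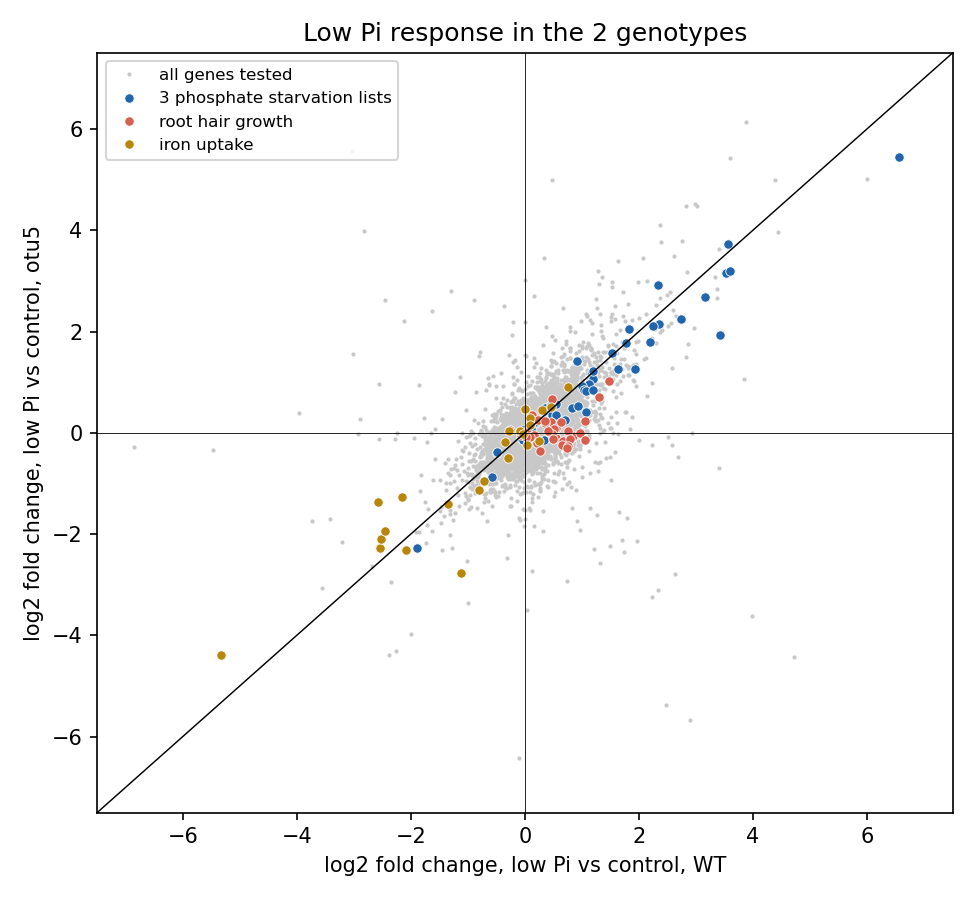
Log2 fold change between low Pi and control in WT (horizontal axis) and in *otu5* (vertical axis), with 1 point per tested gene and the line where the genotypes are equal. IPS1 lies at 6.56 in WT and 5.45 in *otu5*, IRT1 at -5.33 and -4.38, and XTH14, a root hair growth gene, at 1.06 and -0.15.

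The comparison of *otu5* with WT in control medium gives the effect of the mutation when Pi is not limiting. VTL5 (AT3G25190), a gene of the vacuolar iron transporter-like family, was lower in *otu5*, at 37.7 ± 7.64 against 129 ± 13.2 RPKM (SD, n = 3; log2 difference -1.78, SE 0.18, limma adjusted p = 0.0014). The nitrate transporter gene NRT2.2 was higher, at 5.03 ± 1.6 against 0.197 ± 0.159 RPKM (log2 difference 2.97, SE 0.25, adjusted p = 0.00063), and so was the nitrate reductase gene NIA2, at 522 ± 23.2 against 310 ± 23.6 RPKM (log2 difference 0.75, SE 0.11, adjusted p = 0.0028). NRT2.1, the main high-affinity nitrate transporter gene, was at 889 ± 121 RPKM in *otu5* and 402 ± 141 RPKM in WT, and lost its call without WT control replicate 3 (adjusted p = 0.054). The iron peptide gene IMA3 was higher, at 9.66 ± 1.63 against 0.911 ± 0.837 RPKM (log2 difference 3.08, SE 0.5, adjusted p = 0.0061). It is listed at 0 in WT control replicate 3, without which the difference was 2.45. The coumarin gene CYP82C4 was lower, at 0.799 ± 0.0977 against 2.51 ± 0.304 RPKM. CYP76C5, a cytochrome P450 gene, was higher by 3.27 on the log2 scale (SE 0.32, adjusted p = 0.00099).

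Meristem and cell cycle genes were lower in *otu5* in control medium. Of 22 tested, 10 were lower and 0 higher (13 and 0 adjusted over the list alone; camera adjusted p = 4.4e-06, and adjusted p = 0.97 with an estimated correlation). KN, the syntaxin of the dividing cell plate, was at 56.5 ± 2.54 RPKM in *otu5* and 75.6 ± 2.12 RPKM in WT (log2 difference -0.42, SE 0.07, adjusted p = 0.0066). Photosynthesis genes were higher as a list, with 9 of 28 higher and 0 lower (13 and 1 adjusted over the list alone; camera adjusted p = 4.4e-06, and adjusted p = 0.97 with an estimated correlation). LHCB2.2, a light-harvesting protein gene, was at 33.6 ± 2.05 against 17.5 ± 2.79 RPKM and RCA at 138 ± 5.57 against 95.9 ± 10.2 RPKM. Iron storage genes were lower, 2 of 6 with 0 higher (3 and 0 adjusted over the list alone; camera adjusted p = 0.0039, and adjusted p = 0.97 with an estimated correlation), and the list lost its camera call with no filter (median log2 difference -0.23). With VTL5 the other was VTL2 (-0.84, SE 0.24, adjusted p = 0.05), which lost its call without each of the 6 libraries (adjusted p from 0.059 to 0.15). It did so too with a pseudocount of 0.1 (0.055), no filter (0.067), quantile normalization (0.054), limma without trend and robust estimation (0.058), library weights (0.056) and a fit of only these 6 libraries (0.076). The photosynthesis list's mean level differed by 0.32 on the log2 scale (exact permutation p = 0.1), the endodermis list's by -0.27 (exact p = 0.1) and the suberin list's by -0.12 (exact p = 0.5).

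No other list passed camera in control medium. Among 18 nitrate genes 4 were higher and 2 lower (6 and 5 adjusted over the list alone; camera adjusted p = 0.34), among 24 iron uptake genes 4 and 1 (5 and 5; 0.93), and among 22 genes of Pi signalling and transport 1 and 0 (1 and 0; 0.16). Of the 34 root hair growth genes 0 passed in limma (6 at an unadjusted p under 0.05) and the list had a camera adjusted p of 0.39. In 13 scavenging genes 1 was higher (2 adjusted over the list alone), the ribonuclease gene RNS1 with a log2 difference of 1.11 (SE 0.23, adjusted p = 0.016). Of 32 genes of the DNA methylation machinery 1 was higher (1 adjusted over the list alone; camera adjusted p = 0.16), NRPD2, a shared subunit of the RNA polymerases of RNA-directed DNA methylation (log2 difference 0.35, SE 0.05, adjusted p = 0.0044). In the endodermis list 1 of 10 was lower (1 adjusted over the list alone; camera adjusted p = 0.15), the Casparian strip gene CASP5 at 0.738 ± 0.35 against 2.99 ± 0.757 RPKM. Of 16 ethylene genes 2 were higher and 1 lower (5 and 2 adjusted over the list alone), and the ethylene synthesis gene ACO1 was at 320 ± 46.6 against 177 ± 19 RPKM. The lower one, EBF2 (-0.36, SE 0.1, adjusted p = 0.045), lost its call without each of the 6 libraries (adjusted p from 0.074 to 0.14), with no filter (0.06) and with limma without trend and robust estimation (0.059).

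limma called 2117 genes in control medium, 990 higher and 1127 lower in *otu5*, and 121 and 52 of them differed by at least 2-fold. The count was 1060 or 813 without WT control replicate 1 or 3, 781 or 702 without *otu5* control replicate 2 or 3, and 6795 with estimated library weights. With each library left out in turn 1 to 7 meristem genes and 1 to 2 iron storage genes were lower, against 10 and 2. Of photosynthesis genes 3 to 9 were higher against 9, of iron uptake genes 1 to 3 against 4 and of nitrate genes 2 to 7 against 4. The lowest of these counts were reached without WT control replicate 3, among others. Of DNA methylation genes 1 to 3 were higher against 1, of ethylene genes 1 to 2 against 2 and of Pi signalling and transport genes 0 to 1 against 1, while 0 to 2 nitrate genes, 1 to 2 iron uptake genes and 1 to 2 endodermis genes were lower against 2, 1 and 1.

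The comparison of *otu5* with WT in low Pi gives the effect of the mutation under Pi limitation. VTL5 was again lower, at 34.9 ± 6.41 against 140 ± 24 RPKM (SD, n = 3; log2 difference -1.98, SE 0.18, limma adjusted p = 0.00057). Root hair growth genes were lower in *otu5*. RHS19, a peroxidase gene of root hairs, was at 54.7 ± 9.61 against 147 ± 36 RPKM (log2 difference -1.41, SE 0.17, adjusted p = 0.0014), XTH14 at 86.6 ± 9.79 against 197 ± 40.7 RPKM, and COW1, which is needed for hair tip growth, at 8.37 ± 0.738 against 18.8 ± 4.61 RPKM. The wall enzyme gene XTH26 was at 5.73 ± 2.04 against 29.6 ± 9.83 RPKM (log2 difference -2.28, SE 0.27, adjusted p = 0.0014). UGT74E2, a glucosyltransferase gene that acts on an auxin precursor, was higher, at 21.2 ± 7.46 against 3.93 ± 2.17 RPKM (log2 difference 2.35, SE 0.33, adjusted p = 0.0029).

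Of 34 root hair growth genes 18 were lower and 0 higher in *otu5* low Pi (22 and 0 adjusted over the list alone; camera adjusted p = 2.4e-12, and adjusted p = 0.84 with an estimated correlation). Of 22 meristem and cell cycle genes 9 were lower and 0 higher (12 and 0 adjusted over the list alone; camera adjusted p = 2.6e-05, and adjusted p = 0.84 with an estimated correlation). CDKB2;1, a mitotic kinase gene, was at 27.7 ± 2.43 against 37.8 ± 2.01 RPKM, and the ribonucleotide reductase gene TSO2 was lower as well (log2 difference -0.41, SE 0.07, adjusted p = 0.0057). TSO2 lost its call in 1 alternative other than a left-out library. Of 6 iron storage genes 3 were lower and 0 higher (4 and 0 adjusted over the list alone; camera adjusted p = 0.00033, and adjusted p = 0.84 with an estimated correlation). With VTL5 these were VTL2 and FER3. VTL2 lost its call without WT low Pi replicate 1 or 2 (adjusted p = 0.1 for each) or *otu5* low Pi replicate 1 or 2 (0.096 and 0.063), and FER3 without WT low Pi replicate 1 or 2 (0.099 and 0.054) or *otu5* low Pi replicate 1 or 3 (0.1 and 0.068). Of 32 genes of the DNA methylation machinery 3 were higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.0038, and adjusted p = 0.84 with an estimated correlation). NRPD2 was at 16.1 ± 0.724 against 11.8 ± 0.268 RPKM, and DML3, a DNA demethylase gene, at 2.12 ± 0.182 against 1.22 ± 0.0638 RPKM. DML3 too lost its call in 1 alternative other than a left-out library.

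Photosynthesis genes were higher as a list in *otu5* low Pi, with 3 of 28 higher and 0 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0069, and adjusted p = 0.88 with an estimated correlation). The endodermis list was lower, with 0 higher and 1 of 10 lower (0 and 3 adjusted over the list alone; camera adjusted p = 0.035, and adjusted p = 0.84 with an estimated correlation). The anthocyanin list was lower too, with 0 higher and 1 of 13 lower (0 and 5 adjusted over the list alone; camera adjusted p = 0.04, and adjusted p = 0.88 with an estimated correlation). The mean level of the photosynthesis list differed by 0.2 on the log2 scale (exact permutation p = 0.2), that of the endodermis list by -0.27 (exact p = 0.1) and that of the suberin list by 0.17 (exact p = 0.3). Of 18 nitrate genes 5 were higher and 1 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.2), with NRT2.2 at a log2 difference of 1.53 (SE 0.25, adjusted p = 0.0053). Of 24 iron uptake genes 4 were higher and 0 lower (4 and 0 adjusted over the list alone; camera adjusted p = 0.18). In the Pi lists 1 of 22 signalling and transport genes was higher and 1 lower (1 and 1 adjusted over the list alone), 1 of 13 scavenging genes was higher, and 0 of 17 lipid remodelling genes passed in limma (1 at an unadjusted p under 0.05), with camera adjusted p values of 0.78, 0.98 and 0.77. The higher ones were WRKY6 (0.39, adjusted p = 0.029) and PAP3 (0.6, adjusted p = 0.034) and the lower one was PHO2 (-0.26, adjusted p = 0.017). Without WT low Pi replicate 1 or 2 or *otu5* low Pi replicate 1 all 3 lost their calls, as they did in a fit of only these 6 libraries (adjusted p = 0.12, 0.1 and 0.06). WRKY6 also lost its call without *otu5* low Pi replicate 2 (0.064) and PAP3 without *otu5* low Pi replicate 3 (0.092), and PHO2 with quantile normalization (0.075). Of the signalling and transport genes 6 were lower without WT low Pi replicate 3, 2 without *otu5* low Pi replicate 2 and 0 in the 3 left-out fits where all lost their calls. Of 14 sulfate genes 1 was higher and 1 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.69). These were the transporter genes SULTR1;2 (log2 difference 0.56, SE 0.11, adjusted p = 0.011) and SULTR1;1 (-1.41, SE 0.17, adjusted p = 0.0014). Of 19 auxin genes 1 was higher and 1 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.78), GH3.6 (0.44, SE 0.09, adjusted p = 0.011) and IAA19, at 5.09 ± 0.743 against 9.03 ± 0.54 RPKM. In a fit of only these 6 libraries SULTR1;2 and GH3.6 did not pass (adjusted p = 0.057 and 0.069). Of 6 reference genes 1 was higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.74), UBQ10 at 1740 ± 122 against 1340 ± 11.9 RPKM and ACT2 (-0.3, SE 0.08, adjusted p = 0.032). ACT2 lost its call without WT low Pi replicate 1 or 2 (adjusted p = 0.11 and 0.08), *otu5* low Pi replicate 1 or 3 (0.11 and 0.078), with quantile normalization (0.096) and in a fit of only these 6 libraries (0.11).

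limma called 2023 genes in low Pi, 817 higher and 1206 lower in *otu5*, and 83 and 132 of them differed by at least 2-fold. The count was 832 or 945 without WT low Pi replicate 1 or 2, 830 without *otu5* low Pi replicate 1, 4382 with estimated library weights and 502 in a fit of only these 6 libraries. The photosynthesis list lost its camera call without WT low Pi replicate 1 (median log2 difference 0.11), the DNA methylation list without *otu5* low Pi replicate 3 (0.05), the endodermis list without WT low Pi replicate 1, *otu5* low Pi replicate 2 or *otu5* low Pi replicate 3 (-0.15, -0.2 and -0.21), and the anthocyanin list without WT low Pi replicate 2, *otu5* low Pi replicate 1 or *otu5* low Pi replicate 3 (-0.32, -0.28 and -0.23). With no filter the iron storage list (-0.28) and the anthocyanin list (-0.08) lost their calls, and with the filter of 5 RPKM the anthocyanin list (-0.22) and the endodermis list (-0.14) did. With each library left out in turn 3 to 12 meristem genes were lower against 9, 1 to 4 iron storage genes against 3, 0 to 3 endodermis genes against 1 and 0 to 5 anthocyanin genes against 1. Of photosynthesis genes 0 to 7 were higher against 3, of DNA methylation genes 2 to 5 against 3, of iron uptake genes 0 to 3 against 4 and of nitrate genes 2 to 4 against 5. Of nitrate genes 0 to 1 were lower against 1, and of auxin and of sulfate genes 1 to 2 against 1. The lowest of these counts were reached without *otu5* low Pi replicate 1, among others, except that of endodermis genes, which was reached without WT low Pi replicate 1 or 2.

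The effect of the mutation was compared between media across the 20411 genes, and Pearson's r was 0.476 and Spearman's rho 0.602, with no library shared. Among genes called in both media 433 were higher in both and 582 lower in both, against 39.6 and 66.6 for independent lists. Only 2 had opposite signs, against 103.6. The effect of the mutation in control medium was also set against the low Pi response of WT, which uses the same WT control libraries. Pearson's r was 0.322 and Spearman's rho 0.233, where unchanged groups simulated against those controls gave a mean r of 0.499, with a range from 0.396 to 0.599. The simulation drew all libraries independently, while same-numbered WT control and WT low Pi libraries deviated alike (r from 0.114 to 0.259). The covariance was 0.0397 against a mean of 0.0276 and a highest value of 0.0375 in the simulation. In this pair 63 genes were higher in both, against 25.2 for independent lists, 93 were lower in both, against 19.6, and 26 had opposite signs, against 45.9. Since 3 controls cannot be split into parts of at least 2 libraries each, part of the excess may come from the shared controls.

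The difference between the low Pi responses of the genotypes was tested as an interaction. PAL4 (AT3G10340), a phenylalanine ammonia-lyase gene, fell with low Pi in WT, from 22.6 ± 0.337 to 16.7 ± 0.354 RPKM, and rose in *otu5*, from 15.1 ± 1.41 to 20.9 ± 1.04 RPKM (SD, n = 3). The log2 fold changes were -0.43 (limma adjusted p = 0.006) and 0.45 (adjusted p = 0.0033), and the interaction was 0.88 (SE 0.09, adjusted p = 0.025). It was the 1 gene past the threshold, with 1117 at an unadjusted p under 0.05. The next by p, RABA5E (-0.53, SE 0.07, adjusted p = 0.21) and AT5G57655 (0.5, SE 0.08, adjusted p = 0.22), did not pass. The PAL4 call was lost without WT control replicate 1 or 3 (adjusted p = 0.15 and 0.16), WT low Pi replicate 1 or 2 (0.063 and 0.11), *otu5* control replicate 2 or 3 (0.052 and 0.08) or *otu5* low Pi replicate 1 (0.15). The count of genes was 3, 17 or 5 without WT control replicate 2, WT low Pi replicate 3 or *otu5* low Pi replicate 3, and 147 with estimated library weights. With the replicate number as a block it was 0.

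Of the 34 root hair growth genes 29 had a negative interaction, between -1.21 and 0.32 over the list, with a median of -0.44. None passed in limma over all genes, 20 were negative at an unadjusted p under 0.05 and 18 were negative adjusted over the list alone. Without WT low Pi replicate 3 limma put 4 members past the threshold over all genes, all negative, and without any other library 0. The list was lower by camera (adjusted p = 2.5e-18, and adjusted p = 0.89 with an estimated correlation). XTH14 had an interaction of -1.21 (SE 0.2, adjusted p = 0.22). Of the 17 members that rose in WT, 2 also rose in *otu5* and 12 were lower in *otu5* than in WT in low Pi. The 12 rest on the same WT low Pi libraries by which the 17 were picked, which favours a high count. The mean level of the list was 4.28 ± 0.07 on the log2 scale in WT control, 4.8 ± 0.21 in WT low Pi, 4.21 ± 0.09 in *otu5* control and 4.27 ± 0.1 in *otu5* low Pi (SD, n = 3). Its interaction was -0.46. Exact permutation gave p = 0.1 over 400 exchanges of genotype labels within the media and p = 0.09 over exchanges of medium labels within the genotypes. These p values decide nothing about the interaction. Exchanging labels in 1 medium or 1 genotype alone turns the difference between genotypes or media into an interaction. The list differed between genotypes by -0.07 in control and -0.53 in low Pi, so the smallest p of 0.005 could not be reached. Camera put 5 other lists past the threshold for the interaction, whose median values were -0.69 for jasmonate (adjusted p = 0.0018), -0.19 for Pi signalling and transport (0.012), -0.1 for photosynthesis (0.012), 0.32 for suberin (0.0028) and 0.24 for xylem (0.0047). With an estimated correlation the adjusted p values were 0.89 for each of these except photosynthesis, which had 0.97. The root hair growth list kept its camera call without each library in turn. The photosynthesis list lost it without WT control replicate 1 (median -0.01), WT low Pi replicate 2 or 3 (-0.03 and -0.09), *otu5* control replicate 3 (-0.06) or *otu5* low Pi replicate 3 (-0.1). Pi signalling and transport lost it without WT control replicate 1 (-0.19), WT low Pi replicate 1 or 2 (-0.13 and -0.19), *otu5* control replicate 1 (-0.15) or *otu5* low Pi replicate 1 or 3 (-0.13 and -0.18), and with no filter (-0.11). Jasmonate lost it without WT control replicate 1 (-0.62) or *otu5* control replicate 1 (-0.46), and suberin without *otu5* control replicate 2 (0.22). Xylem lost it without WT control replicate 2 (0.16), *otu5* control replicate 2 (0.14) or *otu5* low Pi replicate 3 (0.2).

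**Figure D3:**
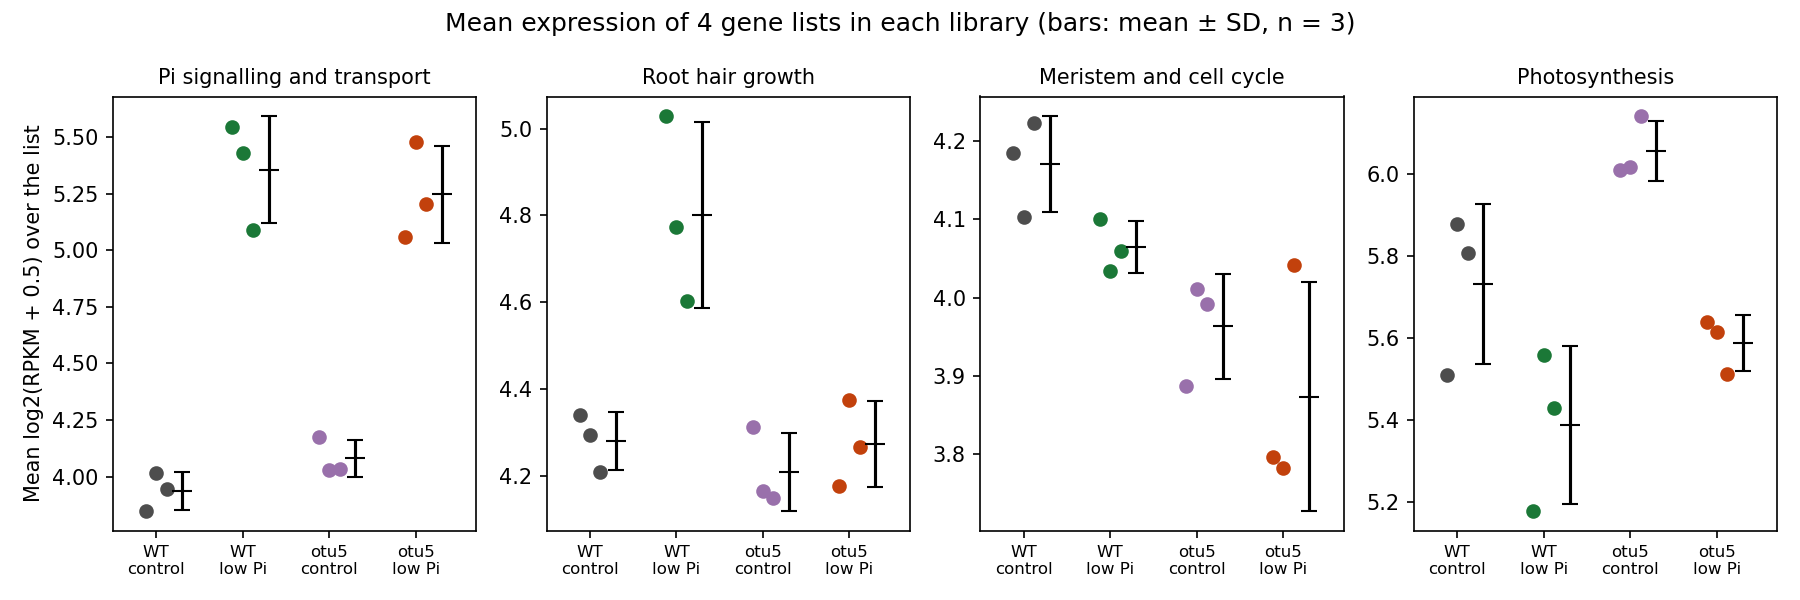
Mean log2(RPKM + 0.5) over the tested genes of 4 lists (vertical axes, which do not start at 0) in each library, grouped by genotype and medium, with bars for the mean ± SD of 3 libraries. The root hair growth list is at 4.8 in WT low Pi and between 4.21 and 4.28 in the other groups.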

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

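The tests of explanations for the root hair pattern were chosen after its values were seen, as were fry and the relabelling with the mean genotype difference taken off, while the first relabelling counts were chosen before.

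PAL4 and 6 gene lists stood out because their low Pi response differed between WT and *otu5* by the test of the interaction itself. PAL4 had an interaction of 0.88 on the log2 scale (SE 0.09, limma adjusted p = 0.025), and its expression fell with low Pi in WT and rose in *otu5*. The median interaction of the root hair growth list was -0.44 (camera adjusted p = 2.5e-18). It was -0.69 for jasmonate, -0.19 for Pi signalling and transport, -0.1 for photosynthesis, 0.32 for suberin and 0.24 for xylem. None of the 6 lists passed with an estimated correlation, where the smallest adjusted p was 0.89. By fry 0 lists passed, with an unadjusted p of 0.023 for root hair growth.

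Of 100 relabellings of the libraries, the real labels included, 34 gave at least the 1 gene called and 61 gave at least the 6 lists called, and the highest count under other labels was 5204 genes against 1 and 12 lists against 6. These splits decide nothing, because exchanging genotypes in 1 medium turns the difference between the genotypes into an interaction. The count was therefore repeated with the mean genotype difference taken off each gene, which leaves its interaction as it was. Then 13 of 100 gave at least 1 gene and 59 gave at least 6 lists, with highest other counts of 622 genes and 13 lists, so chance cannot be excluded for either count. The source of the count of 622 was not traced.

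Of the root hair growth list, 17 of 34 members rose in WT and 18 were lower in *otu5* than in WT in low Pi. RSL4 was not among the 18. It lay at 6.856 to 10.82 RPKM in *otu5* low Pi and 6.315 to 7.412 RPKM in WT low Pi. Its rise with low Pi in *otu5* was called, and the call was lost in 1 left-out fit and in 1 other alternative. The tables argue against a single library, since the median interaction of -0.44 stayed between -0.54 and -0.34 with each library left out in turn. They argue against library scaling, since quantile normalization gave -0.44 and the median of all genes was 0. A lower share of root hair cells in *otu5* roots under low Pi stays open as a candidate explanation, since neither prediction made for it was met. If it were the cause, nearly all members should lie within 2 SE of the list's median, and 18 of 34 did. If it were not, several members should have a positive interaction adjusted over the list alone, and 0 had. Without counts of hair cells a lower share of them cannot be told apart from weaker expression per cell, which is the biological hypothesis that the genotypes offer and is untested.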

How the results depend on the processing

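Loci under 300 bp left out, fry and the replicate block in WT only were chosen after seeing the data, and all other alternatives were planned.

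No named and called gene and no called list reversed under any alternative run. The differences in mean level of the photosynthesis, endodermis and suberin lists were not checked for a change of sign. OTU5 stayed called in both media under every alternative run, at -4.62 to -4.36 in control and -5.1 to -4.75 in low Pi with libraries left out. The count of 875 genes for WT low Pi lay between 242 and 602 with each library left out, the lowest without WT control replicate 3. For *otu5* low Pi the 1754 genes became 503 to 2494, the lowest without *otu5* control replicate 3. For *otu5* against WT in control the 2117 genes became 702 to 1613, the lowest without *otu5* control replicate 3. In low Pi the 2023 genes became 830 to 2251, the lowest without *otu5* low Pi replicate 1. The single interaction gene became 0 to 17, with 17 without WT low Pi replicate 3, 5 without *otu5* low Pi replicate 3 and 3 without WT control replicate 2. It was 0 without WT control replicate 1 or 3, WT low Pi replicate 1 or 2, *otu5* control replicate 2 or *otu5* low Pi replicate 1. A fit with fewer libraries has fewer degrees of freedom, and the cause of the differences between libraries was not tested. Of 194 named and called results, 107 kept their call without every library and 87 lost it without some library, and 0 changed sign.

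Estimated library weights gave 2005, 7631, 6795 and 4382 genes for the 4 pairwise comparisons and 147 for the interaction, and the cause was not tested. Fits of only the 6 libraries compared gave 855 genes for *otu5* low Pi and 502 for *otu5* against WT in low Pi, with fewer libraries to estimate the spread. The interaction gave 2 genes with no filter and 2 with limma without trend and robust estimation, and the cause was not tested. Counts of genes changed by at least 2-fold moved from 194, 300, 173 and 215 to 318, 548, 304 and 346 with library weights, and the last of them to 142 with the filter of 5 RPKM. With only the 6 libraries the counts of 300 and 215 became 185 and 114. Without WT control replicate 1 or 3 or WT low Pi replicate 2 the count of 194 was 127, 100 or 112. That of 300 was 151 without *otu5* control replicate 3 and 180, 173 or 471 without *otu5* low Pi replicate 1, 2 or 3. That of 173 was 114 without WT control replicate 1, and that of 215 was 129 or 328 without WT low Pi replicate 1 or 3. Pseudocounts, median-ratio scaling and quantile normalization moved no count of genes by over 1.5 times, and the scalings shifted the median of all genes by at most 0.025. Median-ratio scaling could change little, since its factors lay between 0.9991 and 1.001. Quantile normalization put 47.1% of calls higher for *otu5* against WT in low Pi, against 40.4%. With loci under 300 bp left out the counts were 909, 1819, 2168, 2078 and 1.

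With the replicate number as a replicate block limma called 735, 1473, 1887, 1798 and 0 genes, the last against 1117 interactions at an unadjusted p under 0.05 without the block (PAL4 had an adjusted p of 0.078). Outside the WT comparison the values gave no uniform sign of pairing by number and do not settle it. Between WT control and *otu5* low Pi, same-numbered libraries had r of 0.001, 0.227 and 0.111, and other libraries r from -0.193 to 0.095. Between WT low Pi and *otu5* low Pi, r reached 0.204 for the same number and 0.254 for unlike numbers. The lowest correlation of same-numbered libraries lay between -0.152 and 0.001 in the 5 other pairs of groups. Over all groups the mean r was 0.023, and 6 of 18 pairs were over 0.1. Of 12 libraries 6 had their highest r with their own number, and 0 correlated best with it in all 3 other groups. With the replicate block in WT only limma called 946 genes for WT low Pi, 723 of them among the 875, and 15 lists passed against 15. CYP82C2 (3.87, adjusted p = 0.069), FER4 (0.55, adjusted p = 0.06) and the iron storage list did not pass, the root hair fate list did, and no other gene named by the fixed rule and no other list changed its call.

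With an estimated correlation 0 lists passed camera in each of the 5 tests, against 15, 11, 3, 7 and 6 with the preset, because correlated members widen the null. fry, which asks another question, put 7, 8, 0, 2 and 0 lists past the threshold. With libraries left out the lists numbered 14 to 17, 10 to 12, 3 to 7 (7 without *otu5* control replicate 1), 4 to 7 (4 without *otu5* low Pi replicate 3) and 3 to 13. The last was 3 without WT control replicate 1 or *otu5* low Pi replicate 3 and 13 without *otu5* low Pi replicate 2. No filter ended 4 of 42 list calls and the filter of 5 RPKM ended 2. The unknown absolute depth limits genes near 1 RPKM most.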

Other observations

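The lists of mitochondrial stress, DNA damage and shoot genes were written after the largest changes were seen, and 4 hypotheses of this kind were tried. The tests of the culture and tissue labels, of mitochondrial stress, of DNA damage, of a linked segment and of a single library were all chosen after the result they bear on, while the shoot test and the splits were chosen before.

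Genes known to respond to mitochondrial dysfunction were among the larger differences between *otu5* and WT. The alternative NAD(P)H dehydrogenase gene NDB4 was at 2.34 ± 0.802 RPKM in *otu5* control roots and 0.426 ± 0.126 RPKM in WT (SD, n = 3; log2 difference 1.58, SE 0.22, limma adjusted p = 0.0029), and the log2 difference in low Pi was 1.54. AT2G21640 was at 23.5 ± 3.27 against 8.36 ± 0.359 RPKM in control and AT5G09570 at 4.68 ± 0.657 against 1.31 ± 0.186 RPKM. NAC13, a regulator of this response, was higher in *otu5* by 0.66 in control (SE 0.12, adjusted p = 0.0078) and by 0.87 in low Pi (SE 0.12, adjusted p = 0.0022). The sulfotransferase gene SOT12 was at 51.5 ± 8.22 against 22.0 ± 2.79 RPKM in low Pi. AOX1A, the best-known gene of the response, did not pass in either medium, with log2 differences of 0.24 and 0.5. A candidate explanation is a wider mitochondrial stress response in *otu5*. Of the 10 tested members that were not among the largest changes, 3 were higher in control and 4 in low Pi and 0 were lower (4 and 5 higher, and 0 and 1 lower, adjusted over the list alone). Their medians were 0.35 and 0.51 (camera p = 0.024 and 0.0018), and the p values with an estimated correlation were 0.38 and 0.24, so that the list did not pass that test.

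The DNA damage regulator genes NAC044 and NAC103 were higher in *otu5* in control medium, by 1.04 (SE 0.11, limma adjusted p = 0.0013) and 1.56 (SE 0.14, adjusted p = 0.00063). The tables argue against a rise of the DNA damage list as a whole, while a response of part of it stays open. The median of the 14 other members tested was 0.06 in control medium (SD of members 0.26), against 1.04 for the smaller change of the pair there, and 0.01 in low Pi (SD 0.27), against 1.01. The pair was picked for its large change, so its distance from the other members was partly set in advance. Of the other members GMI1 and RNR1 were higher in control. The 1 member higher in low Pi was GMI1 (log2 difference 0.76, SE 0.14, limma adjusted p = 0.0095). Around OTU5 no excess of called genes was seen, since 0 of the 40 nearest tested genes were called in both media, where the genome's share was 4.97%. A linked segment from the mutant's parent stays open, because such a segment need not change the expression of its genes.

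Photosynthesis genes had a median log2 difference of 0.31 between *otu5* and WT in control medium, and the tables argue against a single library, since the median stayed between 0.21 and 0.36 with each library left out. Shoot tissue carried over into the root samples stays open: the 5 of 10 shoot genes that could be tested had a median of -0.15 (standard error of the mean 0.12), which met the bound set against it. That bound was wrong as a test, because these genes had a median of 8.55 RPKM in WT control roots, which would hide a small share of shoot. TGG1 was at 0.399 ± 0.243 against 0.13 ± 0.113 RPKM and TGG2 at 0.239 ± 0.113 against 0.0508 ± 0.0685 RPKM, while CER1 was at 0.439 ± 0.272 against 0.518 ± 0.217 RPKM and WSD1 and FAMA were listed at 0 in all 12 libraries, values under the filter that were not tested. RBCS1A, among the most abundant photosynthesis genes, was at 288 ± 22.7 RPKM in the WT control roots themselves, and a biological effect of the genotype was not tested separately.

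The culture condition label of 6 RNA libraries contradicts the title, and the tables argue against titles that are wrong on the medium. Over 35 genes of Pi signalling and scavenging the median log2 difference between libraries titled low Pi and control was 1.01 in WT and 0.83 in *otu5*, where the culture label would put both sets of libraries in the same medium. The labels also name both roots and rosette leaves. The tables argue against RNA from rosette leaves alone, since the lowest library median over the root hair growth, endodermis and suberin lists was 15.5 RPKM. Some leaf material among the roots stays open.

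Other splits of the 6 libraries of each comparison are too few for a share under 0.05, since there are 10. The highest count under another split was 2 genes against 875 for WT low Pi and 1 against 1754 for *otu5* low Pi. It was 2 against 2117 for *otu5* against WT in control and 4 against 2023 in low Pi. In each, 1 of 10 splits, the real one, was as high. The groups of the other splits mix both conditions, so a real difference widens their spread and lowers their counts of genes. Those counts therefore do not measure what chance gives. For gene lists the highest other splits gave 11 against 15, 15 against 11, 12 against 3 and 11 against 7, with 1, 2, 6 and 5 of 10 splits as high as the real one. For WT low Pi, 3 other splits part all 3 same-numbered pairs as the real one does and gave at most 1 gene and 10 lists. The 6 that part 1 pair gave at most 2 genes and 11 lists.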
